A study of Mytilus galloprovincialis with 60 samples.

How the data were processed

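Digestive gland RNA of 60 female mussels, 6 in each of 10 groups, was hybridised singly to custom Agilent arrays in one colour (Cy3), per the labels. Each array file holds the scanner's spot intensity, which the authors obtained with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed signal is an intensity corrected for background and for trends over the array, with no normalization between arrays, and dim spots carry a small positive surrogate. The authors also deposited a table of log2 values for 44773 probes, of which 40510 had values in all 60 arrays, 1300 in autumn only and 2963 in spring only. Set against the scanner signals, each probe of that table is on a log2 scale and centred on its mean over the arrays, with column medians from -0.036 to 0.066. How that table was normalized between arrays and which model the authors fitted are not given in the sources used here. The series design states 7806 identified genes.

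Each array had 59539 spots other than 1853 controls, for 59314 probes. Spots of a probe were averaged. Log2 processed signals were scaled by subtracting each array's 75th percentile. Probes belong to 25753 targets, of which 17940 have a probe on each strand, 7803 have 3 probes on 1 strand and 10 have replicated spots of 1 probe. Where the probes of a pair overlapped they lay on opposite strands in 981 cases and on the same strand in 1 (20 shared bases). The probes of a pair are thus not repeat measurements of the same strand. A target was represented by the probe with the highest mean over the 60 arrays. Targets well above background on at least 6 of the 60 arrays were tested (22692). No spot used was saturated. Where a group had a target well above background on 0 arrays, the fold is a lower bound. The bound allows for background signal at the probe used, and not for sampling error. It sets the mean of the brighter group against the dimmer group's mean of the lowest signal among probes well above background on each array, or of the probe's own signal where that was higher.

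A limma model (limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table) held a mean per group over all 60 arrays, with 50 residual degrees of freedom. Contrasts gave exposed minus control, 10 minus 1 ug/L, spring minus autumn controls, 21 d minus 1 d controls, and the interactions of exposure with season (autumn minus spring) and time (21 d minus 1 d). Tests were two-sided, with Benjamini-Hochberg adjustment over all targets and a threshold of 0.05. Files were read and plots drawn with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The model was tested on simulated data made from the measured means and spreads, and with no change simulated it made 0 calls.

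The design, the filter, the choice of named targets and the alternatives were fixed before the data were examined, except where said otherwise. For exposure and control comparisons, named targets past the threshold were to be named, up to 12 in each direction. Where fewer than 5 passed, the 5 of smallest unadjusted p in each direction were added as values that did not pass. For the interactions and doses, up to 5 named targets past the threshold in each direction were to be named, or else the one of smallest p in each direction. The contig identifiers given in the text fall outside that rule and were chosen after their values were seen, as the largest changes.

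Of 27 gene lists set up in advance by words in gene names, such as metal handling, antioxidant enzymes, lysosome and apoptosis, 25 matched no target. The files give every target the description Unknown, and 0 of the 25753 identifiers matched the reference table of gene symbols. The digestive enzyme list matched 45Meelastase alone and the cytoskeleton list 14Mgalphatubulin alone, so 0 lists reached 5 targets and none was tested. The 12 F-named and 10 measured M-named mitochondrial targets were formed into lists after the data had been seen. They were tested with limma's camera at its preset correlation, with the correlation estimated from the data, and with fry, adjusted over both lists and the comparisons of a family (6 exposure, 4 control and 7 other comparisons). Under the alternative settings given next, the lists were tested with camera at its preset correlation only.

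The alternatives were normexp background correction (offset 50) of the mean signal, quantile normalization, no filter, a filter of 30 arrays, the slide as a fixed term, array weights, only the groups compared in the fit, the mussel number as a block, the authors' value table, and every probe tested separately. Added later were fits without the 2 arrays of lowest share well above background, without the 2 mussels of high M-named signal, without each mussel of the spring 10 ug/L 21 d comparison in turn, and within each scan day. Each slide held up to 8 arrays, and the 8 slides were scanned on 2 days. Principal components were taken of 22462 targets with values on all arrays. Spring differences of both doses against their shared controls were set against 100 simulations of unchanged groups and 20 splits of the controls.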

Results

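RNA of the digestive gland, the organ in which a mussel digests its food, was measured on 60 one-colour arrays, each hybridised with the RNA of 1 female mussel. The mussels had eaten microalgae (Isochrysis galbana) kept for 24 h without silver or with silver nanoparticles of 5 nm coated with the polymers PVP and PEI, at 1 or 10 ug Ag/L. There were 10 groups of 6 mussels. In autumn, controls and the 10 ug/L dose were sampled after 1 and 21 d, and in spring controls, 1 ug/L and 10 ug/L after 1 and 21 d. The signal at each array's 75th percentile lay between 146.3 and 336.2 units, and 43.3 to 67.4% of probes (median 61.3%) were well above background. The lowest share was in autumn 10 ug/L 21 d mussel 3 and the next, 48.4%, in autumn control 21 d mussel 2. The arrays of a group correlated at 0.8456 to 0.8999 across targets. Between 10 spots of a probe on an array the median SD was 0.079 log2 units (25 targets), against 0.356 between the mussels of a group for the same targets. Over all targets measured the latter was 0.595. The number of arrays per group limits the precision of every difference below. Per the labels, the animals of a treatment came from a control tank or a treatment tank, so tank and exposure cannot be told apart, and each season was a single collection.

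Of 25753 targets on the array, 22692 were measured. Only 34 targets carry a name in the files, of which 32 were measured, and the others have contig identifiers that the files do not pair with genes. Of the named targets, 12 ended in F and 12 in M, with 10 of the latter measured. Mussels of this genus carry a mitochondrial genome passed on by females and another passed on by males, usually called F and M, although the files do not spell out the suffixes. ATP6 is a subunit of the mitochondrial ATP synthase, COX1, COX2, COX3, COI, COII and COIII are subunits of cytochrome c oxidase, CYTB is cytochrome b, and targets named ND are subunits of NADH dehydrogenase. The 10 nuclear names include ribosomal proteins (36Me40Sribosomal, 21Meribosomal, 64Mgribosomalp0) and the translation factor 113MgEF1alpha. The cytoskeleton is represented by 57Mgactin and 14Mgalphatubulin, the extracellular matrix by 40Mecollagen, cell adhesion by 89Mgcontactinassociated, RNA binding by 93MgRNAbinding and protein digestion by the protease 45Meelastase. The F-named and M-named lists were formed after the data had been seen.

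Season separated the mussels more than exposure did. Along the first principal component, which held 9.3% of the variance of 22462 targets, all 24 autumn mussels lay below 0 (-79.6 to -7.5) and 4 of the 36 spring mussels did (-28.9 to 88.7). The second component held 3.5%. The numbers of targets that differed ran from 0 in most exposure comparisons to 999 between the seasons.

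**Figure D1:**
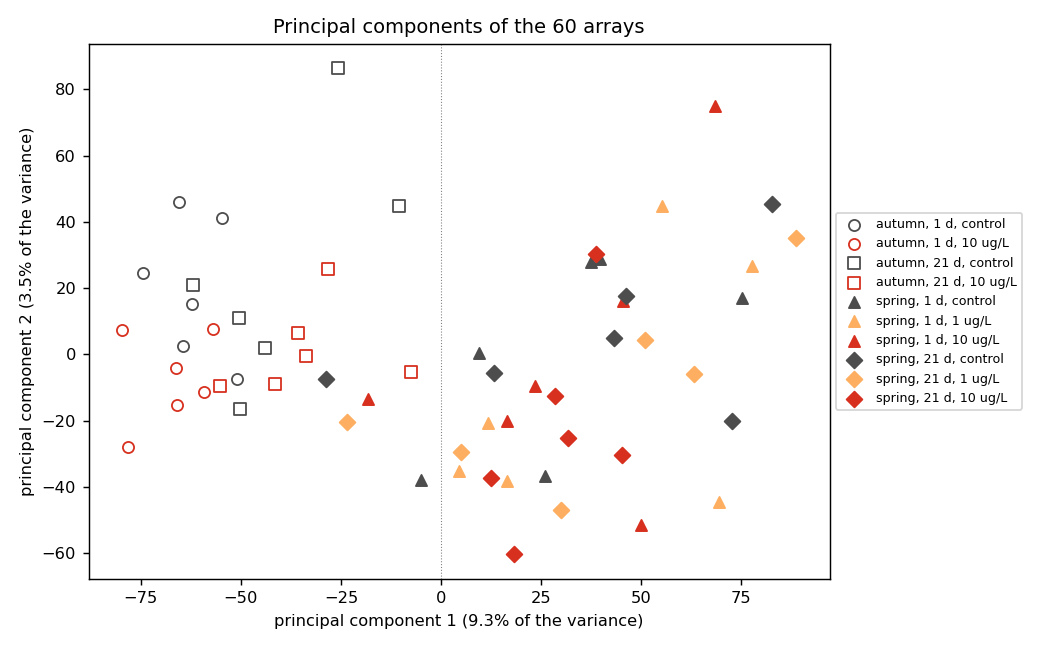
First and second principal components of 22462 targets (each point a mussel, n = 6 per group, axes with their percent of variance). The autumn mussels lie between -79.6 and -7.5 on the first component and the spring mussels between -28.9 and 88.7.

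**Figure D2:**
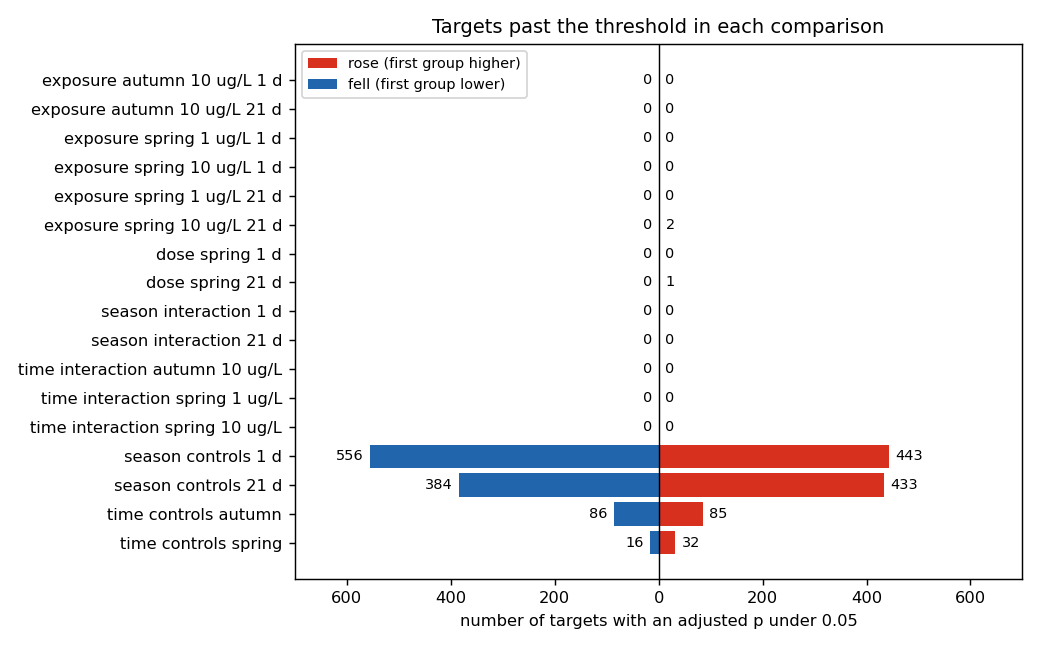
Targets higher and lower at an adjusted p of 0.05 in limma for each comparison, with 6 mussels per group. The seasons differed by 999 targets at 1 d and 817 at 21 d, and the exposure comparisons by 0 to 2.

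In autumn, the first exposure question was what 1 d of feeding on algae from 10 ug/L did to the transcriptome. The F-named mitochondrial transcripts, which encode respiratory chain and ATP synthase subunits, lay higher in exposed mussels in all 12 of 12 targets, by a median of 0.29 log2 units (0.19 to 0.51). Camera gave the list an adjusted p of 1.12e-05 at its preset correlation, an adjusted p of 0.303 with the correlation estimated from the data (0.569), and fry gave 0.324. The mean of the list was 8.53 ± 0.28 in exposed and 8.20 ± 0.43 in control mussels (SD, n = 6). No single target rose or fell: limma called 0 of 22692, with 1206 at an unadjusted p under 0.05 where 1135 were expected, and 1 after quantile normalization or from the authors' value table. ATP6_mgal_F had 9.58 ± 0.25 against 9.13 ± 0.48 (0.45 log2, SE 0.18, adjusted p = 0.888, above the control mean in 6 of 6 mussels). Among values that did not pass, COX2_mgal_F was higher by 0.40, ND4_mgal_F by 0.51 and CYTB_mgal_M by 0.96, and COIII_mgal_M was well above background in 4 of 6 exposed and 0 of 6 control mussels, with exposed mussel 6 the highest at 2.14. The differences were -0.15 for 64Mgribosomalp0, -0.14 for 113MgEF1alpha, -0.79 for 89Mgcontactinassociated, -0.28 for 45Meelastase and -0.09 for 93MgRNAbinding.

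The F-named difference rested largely on autumn control 1 d mussel 7, whose mean of 7.52 was the lowest of the group. Without it the median was 0.16, against 0.24 to 0.44 without any other mussel. Within the first scan day the median was 0.01, and within the second, where mussel 7 was the lone control, 1.26. With the slide as a fixed term the list had an adjusted p of 2.44e-06. The 10 M-named targets were all higher too, by a median of 0.74 (camera adjusted p = 0.00377, adjusted p of 0.303 with an estimated correlation). Mussel 6 of the exposed group had an M-named mean of 1.81 against -0.61 ± 0.35 in the rest of the group (SD). Without that mussel and spring control 1 d mussel 1, which also had high M-named signal, the camera adjusted p was 0.101.

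**Figure D3:**
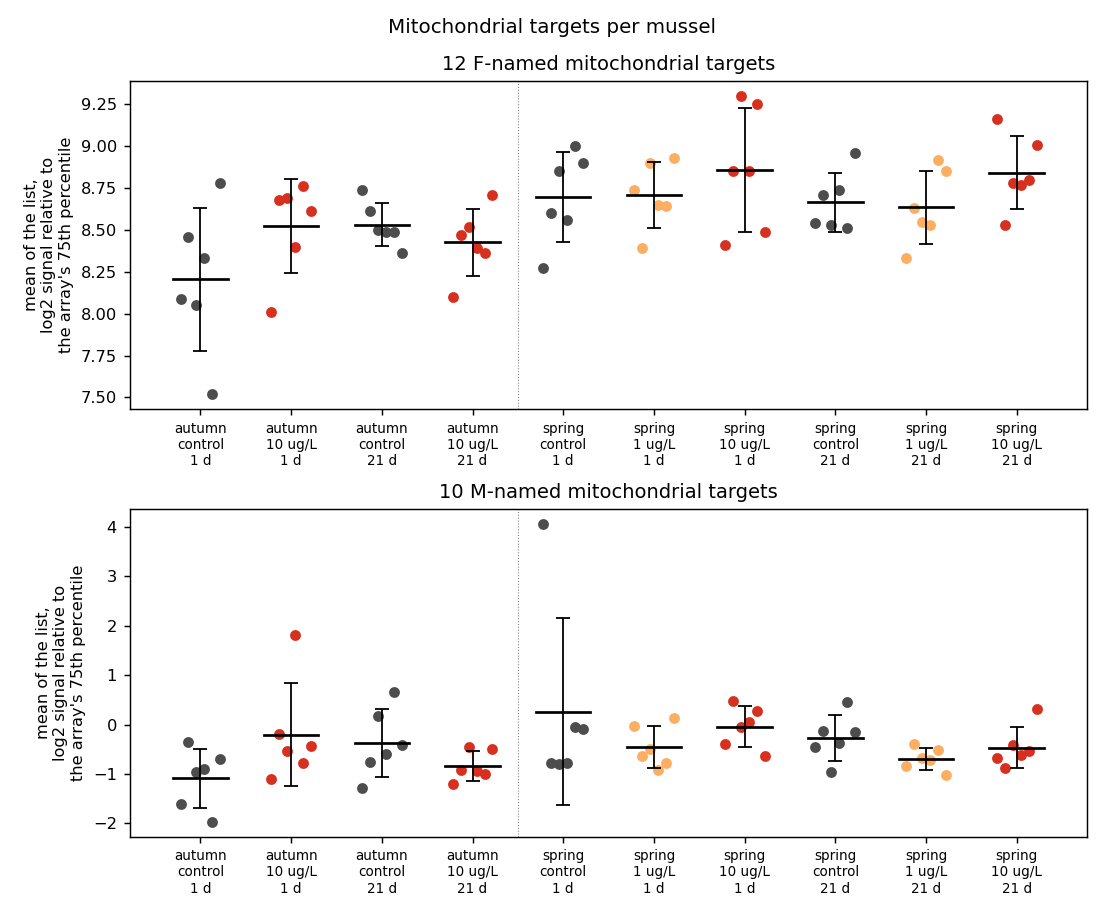
Mean log2 signal of the 12 F-named and 10 M-named mitochondrial targets per mussel, relative to each array's 75th percentile (points are mussels, lines group means, bars SD, n = 6). The M-named means of autumn 10 ug/L 1 d mussel 6 (1.81) and spring control 1 d mussel 1 (4.07) stand above their groups.

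After 21 d of the same autumn exposure, the F-named targets no longer lay higher, with 11 of 12 below the controls by a median of -0.11 (camera adjusted p = 0.123). The change of the exposure effect between 1 and 21 d was tested directly. For the F-named list it was -0.40 in the median, with 12 of 12 targets negative (camera adjusted p = 1.83e-05, adjusted p of 0.449 with an estimated correlation), and -0.01 within the first scan day and -1.45 within the second. For the M-named list it was -0.95 (camera adjusted p = 0.012, adjusted p of 0.537 with an estimated correlation and 0.0858 with normexp). After quantile normalization the F-named fall at 21 d reached a camera adjusted p of 0.00065, and with normexp 0.0361, both at the preset correlation. Without these changes the adjusted p was 0.651 with an estimated correlation and 0.691 with fry. No target rose or fell by itself (limma, 0 calls, 1205 at an unadjusted p under 0.05), and none did by any other setting fitted to both scan days. COIII_mgal_M was at least 2.92-fold lower (well above background in 0 of 6 exposed and 4 of 6 control mussels, adjusted p = 0.816). COI_mgal_M was also lower (-1.43), as were 93MgRNAbinding (-0.18), CYTB_mgal_F (-0.15) and COX3_mgal_F (-0.12), none past the test. Values above the controls were 0.35 for ND2_mgal_M, 0.16 for 21Meribosomal, 0.15 for 57Mgactin, 0.21 for 14Mgalphatubulin and 0.15 for 36Me40Sribosomal, the last -0.01 after quantile normalization and in the authors' value table. In simulated data for this comparison (22462 targets, 50 changed at each size), limma recovered 2 of 50 at 0.5 log2 units, 11 at 1, 36 at 2 and 46 at 4. The changed targets of all sizes lay in the same simulated data and were adjusted together. Many large changes make the threshold easier to pass, so these numbers overstate the recovery of a lone change. In the test of the change between 1 and 21 d limma called 0 targets (1095 unadjusted), with 113MgEF1alpha (0.26) and COIII_mgal_M as the named targets of smallest p. COIII_mgal_M was well above background on 0 of 6 arrays in 2 of the 4 groups, so no size is given.

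In spring, the lower dose of 1 ug/L asked for effects near environmental concentrations. After 1 d the M-named targets lay lower in all 10 of 10, by a median of -0.56 (camera adjusted p = 0.00377, adjusted p of 0.303 with an estimated correlation). This difference rested on spring control 1 d mussel 1, whose M-named mean was 4.07 against -0.50 ± 0.39 in the rest of its group (SD), and without it and autumn 10 ug/L 1 d mussel 6 the camera adjusted p was 0.919. COIII_mgal_M then turned from -1.65 to 0.30, COII_mgal_M from -0.83 to 0.29 and COI_mgal_M from -1.31 to 0.29. The F-named list had a median of -0.01 (camera adjusted p = 0.955). Limma called 0 targets (1046 at an unadjusted p under 0.05) in the comparison as planned. Other values that did not pass were CYTB_mgal_M (-1.01) and 40Mecollagen (-1.13) on the lower side, and 57Mgactin (0.17), 93MgRNAbinding (0.11), ND2_mgal_F (0.22), ND3_mgal_F (0.26) and 21Meribosomal (0.10) on the higher side.

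After 21 d of 1 ug/L, the named targets of smallest p among the higher values were 113MgEF1alpha at 7.73 ± 0.18 against 7.46 ± 0.27 (0.27 log2, SE 0.12, adjusted p = 0.993, above the control mean in 6 of 6 mussels) and 36Me40Sribosomal at 0.19. Neither passed, and limma called 0 of 22692 targets (1055 unadjusted), as did the other settings fitted to both scan days, while 4 rose and 1 fell within the second day alone. ND1_mgal_F (0.14), ND6_mgal_F (0.13) and 21Meribosomal (0.08) were the other higher values. Lower values were -1.40 for ND6_mgal_M, -0.88 for ND3_mgal_M, -0.46 for ND3_mgal_F, -0.15 for 57Mgactin and -0.24 for ND2_mgal_M. The F-named list had a median of 0.04, while camera's direction for it was down (adjusted p = 0.955). No target passed the test of a difference between the 1 d and 21 d effects of 1 ug/L (limma, 0 calls, 861 unadjusted), the named targets of smallest p being 40Mecollagen (1.39) and 57Mgactin (-0.32).

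After 1 d of 10 ug/L in spring, the ribosomal protein targets 21Meribosomal and 36Me40Sribosomal lay above the controls, 21Meribosomal at 7.01 ± 0.17 against 6.74 ± 0.25 (0.28 log2, SE 0.12) and 36Me40Sribosomal at 8.44 ± 0.06 against 8.19 ± 0.20 (0.25 log2, SE 0.11, above the control mean in 6 of 6 mussels). Neither passed, and limma called 0 targets (1057 at an unadjusted p under 0.05), with 1 when only the groups compared entered the fit. Simulated changes for this comparison (22462 targets, 50 per size) were recovered in 5 of 50 targets at 0.5 log2 units, 18 at 1, 35 at 2 and 47 at 4. All sizes were again adjusted together, which overstates the recovery of a lone change. ND2_mgal_F (0.47), ND3_mgal_F (0.51) and ATP6_mgal_F (0.28) were higher without passing, and the F-named list had a median of 0.13 (camera adjusted p = 0.0987). It was 0.19 within the first scan day and -0.27 within the second. With normexp the list's camera adjusted p was 0.0321. The M-named list differed by -0.22 (camera adjusted p = 0.123), past the threshold with normexp (0.0361) and with the slide as a fixed term (0.00906). These passes were at camera's preset correlation. Without normexp or the slide, each list had an adjusted p of 0.651 with an estimated correlation and 0.691 with fry. The direction of the M-named list reversed without the 2 mussels of high M-named signal. The lower values were -0.87 for CYTB_mgal_M, -0.72 for 40Mecollagen, -0.50 for ND4_mgal_M, -0.11 for 93MgRNAbinding and -1.22 for COIII_mgal_M. The last turned to 0.73 without spring control 1 d mussel 1 and autumn 10 ug/L 1 d mussel 6.

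For the 6 mussels of spring 10 ug/L 21 d the source name in the labels says 1 day, while title, description and treatment say 21 d, which was used. After 21 d of 10 ug/L in spring, 2 targets rose and 0 fell, out of 22692 (limma, 1657 at an unadjusted p under 0.05, 1135 expected). The contig mgal_nuc_2301 went from a level near background to 159 times the control mean. It had 3.54 ± 1.09 in exposed and -3.77 ± 1.29 in control mussels (SD, n = 6), a difference of 7.31 log2 units (SE 1.09, limma adjusted p = 0.000315). All 6 of 6 exposed mussels lay above every control. The probe was well above background in 6 of 6 exposed and 4 of 6 control mussels, so the fold of 159 rests partly on background signal. The contig mgal_est_7282 rose by 0.95 (SE 0.18, 1.94-fold, limma adjusted p = 0.0444), from -0.01 ± 0.31 to 0.94 ± 0.42, with 6 of 6 exposed mussels above every control. At its opposite-strand probe the difference was 1.03.

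The probe behind the larger rise, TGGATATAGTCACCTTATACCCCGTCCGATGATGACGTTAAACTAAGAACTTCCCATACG, measured mgal_nuc_2301 well above background on 39 of 60 arrays, and the probe for the other strand of that contig on 0. Leaving out each of the 12 mussels in turn gave 6.83 to 7.61 for mgal_nuc_2301, with adjusted p from 0.000444 to 0.00399. With normexp it was 5.04, and with the slide as a fixed term 7.31. It was 7.34 within the first scan day (limma adjusted p = 0.00183) and 7.55 within the second (adjusted p = 0.102). Among the 54 other mussels, 33 had the probe well above background and 2 exceeded the lowest exposed value of 2.30: autumn 10 ug/L 1 d mussel 1 with 3.88 and spring 10 ug/L 1 d mussel 6 with 3.77. At 21 d in autumn, the exposure difference of mgal_nuc_2301 was -0.12, but the test of the difference between the seasons did not pass (-7.43, SE 1.54, adjusted p = 0.225), nor did that between 1 and 21 d in spring (5.29, adjusted p = 0.991).

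The other call, mgal_est_7282 (probe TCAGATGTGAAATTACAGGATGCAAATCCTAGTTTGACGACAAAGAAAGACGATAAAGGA), lay at the edge of the threshold. It stayed past it in 4 of the 12 fits that left out 1 mussel, with adjusted p from 0.00671 without exposed mussel 2 to 0.232 without exposed mussel 4. The adjusted p was 0.0518 with normexp (0.77), 0.0559 with no filter on dim targets, 0.0635 without the 2 arrays of lowest share well above background and 0.587 with only the groups compared in the fit. With the slide as a fixed term the difference was 0.99 (adjusted p = 0.0283), and within the scan days 1.03 and 0.74 (adjusted p = 0.272 and 0.890). The control level of this contig was lower in spring than in autumn at 21 d (-0.64, adjusted p = 0.0339), and at 1 ug/L it stood 0.77 above the spring controls (adjusted p = 0.497). The number of calls in the comparison was 3 without spring control 21 d mussel 2 or 4. It was 1 without control mussel 5, 7, 9 or 10 or without exposed mussel 4, 7 or 8.

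**Figure D4:**
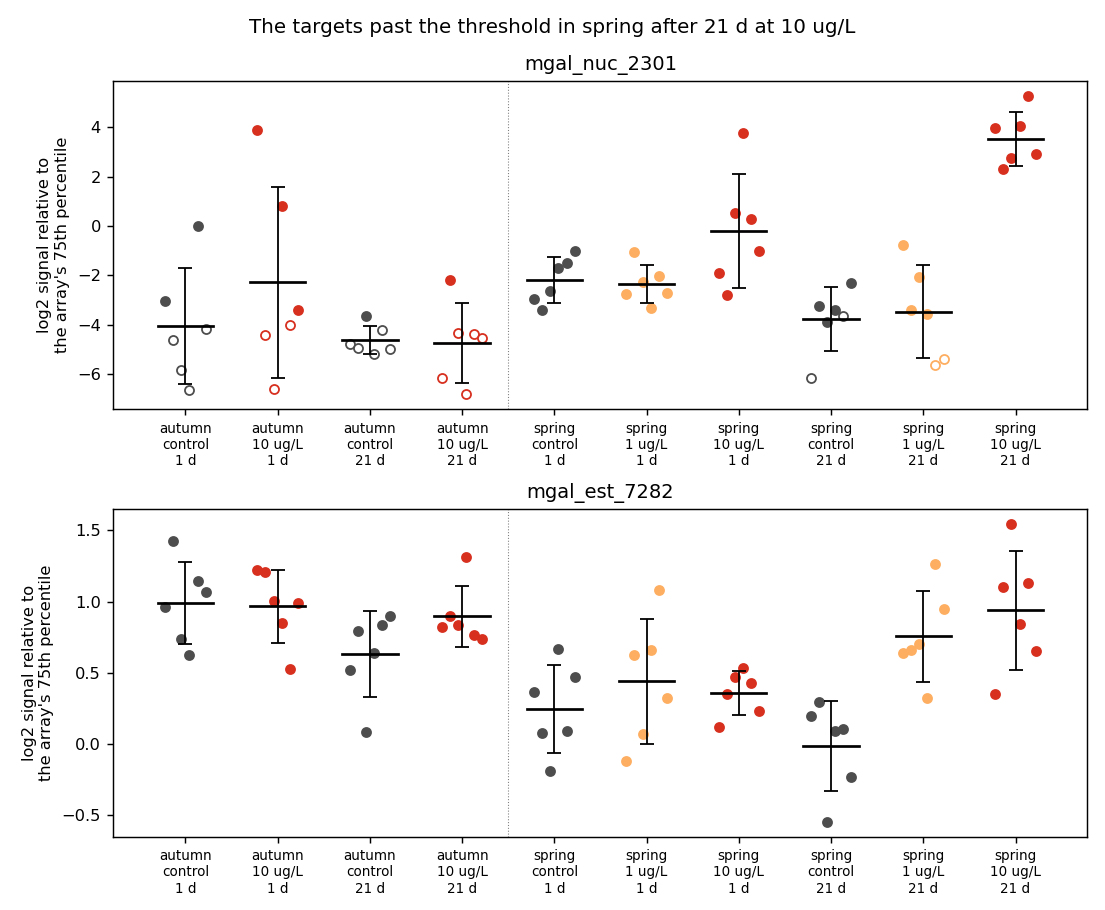
Log2 signal relative to each array's 75th percentile of mgal_nuc_2301 and mgal_est_7282 in every mussel (points are mussels, open circles not well above background, lines group means, bars SD, n = 6). In spring 10 ug/L 21 d, mgal_nuc_2301 averages 3.54 against -3.77 in the controls.

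The named targets after 21 d of 10 ug/L in spring did not pass. Among the higher values, 36Me40Sribosomal differed by 0.27 (8.42 ± 0.23 against 8.14 ± 0.21, SE 0.11, adjusted p = 0.653, above the control mean in 5 of 6 mussels), 113MgEF1alpha by 0.29, 21Meribosomal by 0.25 and 64Mgribosomalp0 by 0.22. ND4_mgal_F was higher by 0.47, and the F-named list by 0.15 in the median (camera adjusted p = 0.0662, or 0.0246 with normexp). With an estimated correlation the camera adjusted p of the list was 0.651, and fry gave 0.691, both without normexp. The lower values were -0.54 for ND2_mgal_M, -0.62 for CYTB_mgal_M, -1.02 for COI_mgal_M, -0.63 for ND6_mgal_M and -0.44 for 89Mgcontactinassociated. In simulated data for this comparison (22462 targets, 50 per size) limma recovered 5 of 50 at 0.5 log2 units, 18 at 1, 36 at 2 and 46 at 4, with 12 false calls. Here too all sizes were adjusted together, which overstates the recovery of a lone change.

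The spring doses were compared with each other to ask for a dose response. At 21 d mgal_nuc_2301 was 129 times as high at 10 ug/L as at 1 ug/L (7.01 log2, SE 1.09, limma adjusted p = 0.000852, 6 of 6 mussels above every 1 ug/L mussel). It was at -3.47 ± 1.88 at 1 ug/L (SD, n = 6), well above background in 4 of 6 mussels, so the size rests partly on background signal. With normexp the difference was 4.92. The difference was 6.80 with the slide as a fixed term, and 6.35 and 8.64 within the scan days (adjusted p = 0.0291 and 0.0528). It was the only target to pass (950 unadjusted). ND3_mgal_F was 0.78 higher at 10 ug/L and ND2_mgal_M differed by -0.29, neither past the test. The F-named list was 0.12 higher (camera adjusted p = 0.0203, adjusted p of 0.732 with an estimated correlation, 0.985 after quantile normalization, 0.0858 with normexp and 0.0511 with the slide as a fixed term). At 1 d limma called 0 targets between the doses (863 unadjusted), 89Mgcontactinassociated being at 1.31 and 93MgRNAbinding at -0.22.

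Both spring doses were set against the same controls, so their differences share the controls' chance values. Across targets they correlated at 0.55 at 1 d and 0.53 at 21 d, against medians of 0.49 and 0.50 in 100 simulations of unchanged groups (0.16 to 0.74 and 0.32 to 0.64). The covariance exceeded the simulated one by 0.004 at 1 d and by -0.003 at 21 d. With the controls split at random between the doses in 20 ways, the correlations had a median of 0.02 at each time. The doses shared 0 calls, which the 0 calls at 1 ug/L make certain (0 and 2 calls at 21 d).

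Whether the 10 ug/L effect differed between autumn and spring was tested as an interaction (autumn effect minus spring effect). Limma called 0 targets at 1 d (1179 unadjusted) and 0 at 21 d (1163 unadjusted), and at 21 d 1 with normexp and 1 when only the groups compared entered the fit. The M-named list differed at 1 d by 0.91 in the median (camera adjusted p = 0.00277, adjusted p of 0.449 with an estimated correlation). The camera adjusted p was 0.79 without autumn 10 ug/L 1 d mussel 6 and spring control 1 d mussel 1. At 1 d the F-named list differed by 0.20 (camera adjusted p = 0.0741), with -0.21 and 1.47 within the scan days. Its adjusted p was 0.0306 after quantile normalization, 0.00964 with the slide as a fixed term and 0.00947 without those 2 mussels. These were at camera's preset correlation. Without these changes the adjusted p was 0.732 with an estimated correlation and 0.708 with fry. The list differed at 21 d by -0.26, with 12 of 12 targets negative (camera adjusted p = 0.00911, adjusted p of 0.732 with an estimated correlation), and by -0.17 and -0.49 within the scan days. The named targets of smallest p were CYTB_mgal_M (1.83) and 21Meribosomal (-0.37) at 1 d, and ND2_mgal_M (0.89) and COIII_mgal_M at 21 d, the last without a size since it was well above background on 0 of 6 arrays in 2 of the 4 groups. No target passed the test of a difference between the 1 d and 21 d effects of 10 ug/L in spring (limma, 0 calls, 1043 unadjusted), although quantile normalization and the authors' value table gave 1 each. The named targets of smallest p there were 40Mecollagen (1.88) and ND2_mgal_M (-0.35).

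Scan day was the batch with several arrays per group: the first held 3 to 5 and the second 1 to 3 of each group, a lone array being assumed to vary like the others. Within the first day limma called 0 targets in each exposure comparison except spring 10 ug/L 21 d, where 1 rose. Within the second, 29 rose and 17 fell in autumn at 1 d, 16 and 11 in autumn at 21 d, 11 and 12 in spring at 1 ug/L and 1 d, 6 and 5 at 10 ug/L and 1 d, 4 and 1 at 1 ug/L and 21 d, and 16 and 7 at 10 ug/L and 21 d. A slide held 1 or 2 arrays of a group, too few for a test within slides.

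Season was compared in the controls, spring minus autumn, to see how far the animals differed before any exposure. At 1 d, mitochondrial transcripts of both lists were higher in spring, and 443 targets were higher and 556 lower (limma, 3761 unadjusted), with a median size of 1.14 log2 units. The F-named list was higher in 12 of 12 targets by a median of 0.49 (camera adjusted p = 1.64e-07, adjusted p of 0.131 with an estimated correlation, fry 0.0088). The M-named list was higher in 10 of 10 by 1.22 (camera adjusted p = 0.00011, adjusted p of 0.131 with an estimated correlation, fry 0.0088). This owed much to spring control 1 d mussel 1, at 4.07 where the rest of the group averaged -0.50, and without it and autumn 10 ug/L 1 d mussel 6 the camera adjusted p was 0.0393. Of the F-named targets, 2 passed over all targets and 9 when adjusted over the list alone.

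Among named targets at 1 d, COX2_mgal_F was higher in spring by 0.52 (9.44 ± 0.17 against 8.93 ± 0.37, SE 0.16, adjusted p = 0.0481) and COX3_mgal_F by 0.50 (9.65 ± 0.13 against 9.15 ± 0.31, adjusted p = 0.0497), each above the autumn mean in 6 of 6 mussels. Both lay at the edge of the threshold: the adjusted p was 0.0748 and 0.0507 with normexp (0.46 and 0.47), 0.0577 and 0.0601 with no filter on dim targets, and 0.195 and 0.156 with only the groups compared in the fit. That of COX2_mgal_F was 0.0509 without the 2 mussels of high M-named signal, and that of COX3_mgal_F 0.0549 with the slide as a fixed term (0.51, SE 0.16 as before) and 0.0534 without the 2 arrays of lowest share well above background. ND2_mgal_M was higher by 0.82 (3.59 ± 0.56 against 2.77 ± 0.20, SE 0.22, adjusted p = 0.0209, 6 of 6 mussels above the autumn mean). Without spring control 1 d mussel 1 and autumn 10 ug/L 1 d mussel 6 it was 0.63 (adjusted p = 0.0965), and with only the groups compared in the fit the adjusted p was 0.122. Without autumn control 1 d mussel 7 the F-named median was 0.35, and it was 0.34 and 1.26 within the scan days. COX1_mgal_F (0.49), ND4_mgal_F (0.74), ND5_mgal_F (0.53), ND1_mgal_F (0.54) and CYTB_mgal_M (1.36) were higher without passing. Of these, COX1_mgal_F (adjusted p = 0.0586) passed with normexp (0.012), a filter of 30 arrays (0.0486), the slide as a fixed term (0.0426), array weights (0.0357) and without the 2 mussels of high M-named signal (0.0374). ND4_mgal_F, ND5_mgal_F and ND1_mgal_F passed with quantile normalization and in the authors' value table (adjusted p from 0.0162 to 0.032), and ND1_mgal_F without those 2 mussels (0.0351). 113MgEF1alpha (-0.33), 21Meribosomal (-0.23), 89Mgcontactinassociated (-0.94), 14Mgalphatubulin (-0.20) and 93MgRNAbinding (-0.12) were lower without passing.

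The widest seasonal contrast at 1 d was in contig mgal_nuc_16063, at 8.52 ± 1.84 in spring and -2.69 ± 0.54 in autumn (11.21 log2, SE 0.94, limma adjusted p = 3.18e-12, 6 of 6 spring mussels above every autumn one). Its other probes gave 11.40 and 12.03, and the slide as a fixed term 11.10. The contig mgal_nuc_16031 was at least 52.4-fold higher in spring (well above background in 5 of 6 against 0 of 6, adjusted p = 0.000647). In the other direction, mgal_est_18418 fell to -0.62 ± 2.75 from 7.98 ± 1.69 (-8.60, SE 1.47, adjusted p = 0.000277, 6 of 6 below every autumn mussel). At its opposite-strand probe the difference was smaller (-4.75, SE 1.10). The contig mgal_nuc_3844 was at least 153-fold lower (well above background in 0 of 6 against 5 of 6, adjusted p = 0.0275, below the autumn mean in 6 of 6 mussels), with autumn mussel 1 apart at -6.44. Its opposite-strand probe gave a smaller -3.51 (SE 1.76). The opposite-strand probe of mgal_nuc_16031 was well above background on 2 of 60 arrays. The 556 lower targets formed 460 groups by shared probe sequence, the largest with 55 targets. Contigs with the prefix mgal_est leaned lower in spring, 215 of 3731 against 46 higher, while those with mgal_nuc did not, with 304 lower and 356 higher of 17419. The difference between the prefixes was not tested, and contigs of shared probe sequence weigh in these counts.

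At 21 d, 433 targets were higher and 384 lower in spring controls (limma, 3336 unadjusted, median size 1.09). ND2_mgal_M was again higher, by 1.09 (3.68 ± 0.66 against 2.59 ± 0.26, SE 0.22, adjusted p = 0.00371, 6 of 6 spring mussels above every autumn one), and by 1.03 with the slide as a fixed term. Within the scan days it was 0.74 (adjusted p = 0.173) and 1.86 (adjusted p = 0.291). The F-named list was higher by 0.15 (camera adjusted p = 0.12). The contig mgal_nuc_16063 had 8.56 ± 1.17 against -2.17 ± 1.81 (10.73, SE 0.94, adjusted p = 1.69e-11, 6 of 6 above every autumn mussel), with 4 of 6 autumn mussels well above background. mgal_nuc_35390 was higher by 4.66 (adjusted p = 0.0141, 6 of 6 above the autumn mean, other probes 4.27 and 3.54), with spring mussel 4 apart at -1.95. Within the scan days the difference of mgal_nuc_35390 was 5.28 and 0.79, the latter with a lone autumn array. The contig was well above background in 6 of 6 against 2 of 6, so the size rests partly on background signal. Both mgal_est_17642 (-6.13, adjusted p = 0.00942) and mgal_est_18418 (-6.05, adjusted p = 0.0112) were lower, with 6 of 6 spring mussels below every autumn one and -5.14 and -4.27 at their opposite-strand probes. With only the groups compared in the fit these were lost (adjusted p = 0.14 for both), as were mgal_nuc_35390 (0.231) and ND2_mgal_M (0.179). Named values that did not pass were 57Mgactin (0.30), CYTB_mgal_F (0.35), COII_mgal_M (0.90), CYTB_mgal_M (0.62) and ND5_mgal_F (0.23) on the higher side. On the lower side they were COIII_mgal_M (at least 3.23-fold lower, adjusted p = 0.184, or 0.0139 without the 2 mussels of high M-named signal), 113MgEF1alpha (-0.24), 93MgRNAbinding (-0.15), 36Me40Sribosomal (-0.12) and 64Mgribosomalp0 (-0.09).

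Most seasonal calls were made at 1 of the times only, though more were shared than independent lists would give: 109 were higher in spring at 1 d and at 21 d (8.45 expected), 187 lower in both (9.41 expected) and 0 opposite. Across all targets the differences at 1 and 21 d correlated at 0.44. The 187 formed 125 groups by shared probe sequence, the largest with 52 targets, so near-duplicate contigs weigh in these counts. In mussels given 10 ug/L, a comparison added after the data had been seen, 955 of the 999 control calls at 1 d (95.6%) and 767 of the 817 at 21 d (93.9%) had the same sign. Their median size there was 0.68 against 1.14 in controls at 1 d and 0.43 against 1.09 at 21 d. Choosing targets by their control values makes a smaller size in exposed mussels likely in any case. The smaller sizes thus do not show a weaker seasonal difference in exposed mussels. In both, 348 (34.6 expected) and 77 (4 expected) passed. In the exposed mussels 363 targets were higher and 423 lower in spring at 1 d, and 7 and 104 at 21 d. In all 4 seasonal comparisons 54 targets passed, 2 of them higher and 52 lower in spring, the 52 forming 17 groups by shared probe sequence with 35 targets in the largest. With the slide as a fixed term 968 targets passed at 1 d and 562 at 21 d. Within the first scan day 379 were higher and 423 lower at 1 d, and 9 and 23 at 21 d. Within the second these numbers were 21 and 9, then 15 and 7. Without autumn control 21 d mussel 2 and autumn 10 ug/L 21 d mussel 3 the count at 21 d was 508, and with only the groups compared in the fit the counts were 439 and 7.

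**Figure D5:**
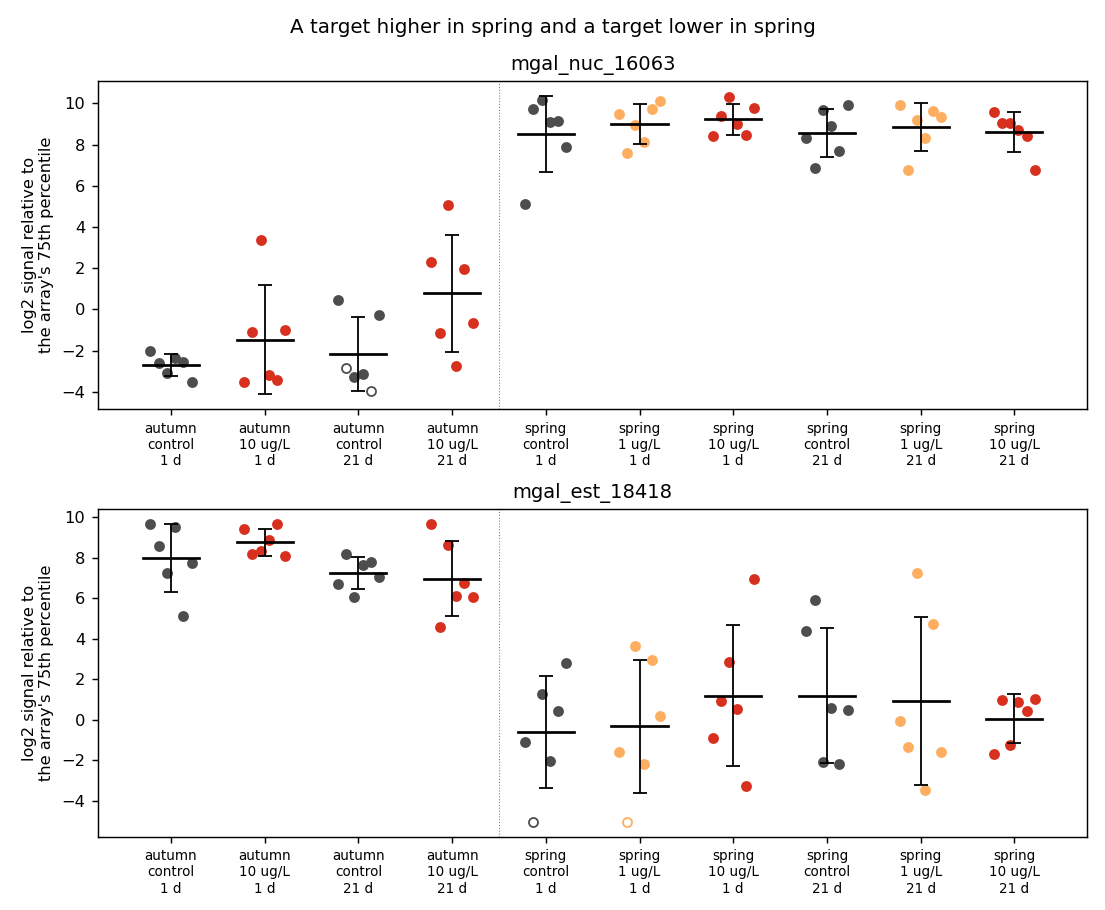
Log2 signal relative to each array's 75th percentile of targets that differed between the seasons, in every mussel (points are mussels, open circles not well above background, lines group means, bars SD, n = 6). mgal_nuc_16063 averages 8.52 in spring and -2.69 in autumn controls at 1 d.

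Time in the laboratory was compared in the controls, 21 d minus 1 d. In autumn 85 targets rose and 86 fell (limma, 2579 unadjusted, median size 0.93), and the F-named transcripts were higher at 21 d in 12 of 12 targets, by a median of 0.32 (camera adjusted p = 0.00011, adjusted p of 0.288 with an estimated correlation, fry 0.0979). Without autumn control 1 d mussel 7 the median was 0.21, and within the scan days it was 0.18 and 0.98. The F-named mean of the autumn controls at 1 d, 8.20, was the lowest of the 10 groups. These controls also enter the autumn exposure and season comparisons at 1 d. They enter the change of the autumn exposure effect between 1 and 21 d as well, so these F-named results are not independent. The M-named list was higher by 0.36 (camera adjusted p = 0.137, or 0.0384 with the slide as a fixed term, and 0.558 with an estimated correlation and no slide term). The contigs mgal_nuc_33049 (4.46, SE 1.02, adjusted p = 0.0222) and mgal_nuc_2868 (4.15, SE 0.91, adjusted p = 0.0170) rose, with 6 of 6 mussels above the 1 d mean. With normexp both were lost, at 2.95 (adjusted p = 0.0907) and 2.70 (adjusted p = 0.0583), and with only the groups compared in the fit the adjusted p was 0.158 and 0.16. Without autumn control 21 d mussel 2 and autumn 10 ug/L 21 d mussel 3 that of mgal_nuc_33049 was 0.0552. Their opposite-strand probes gave smaller rises of 1.48 (SE 0.64) and 1.79 (SE 0.74), well above background on 19 and 29 of 60 arrays. Autumn control 1 d mussel 6 stood apart for both, at 1.82 and 1.77. The contigs mgal_est_5042 (-4.78, SE 0.69, adjusted p = 3.06e-05) and mgal_est_5043 (-3.85, SE 0.66, adjusted p = 0.000974) fell, with 6 of 6 mussels below every 1 d mussel and -3.21 and -2.06 at their opposite-strand probes. With only the groups compared in the fit, however, mgal_est_5043 had an adjusted p of 0.0768. No named target passed. COIII_mgal_M was at least 4.09-fold higher (adjusted p = 0.187, or 0.0187 without the 2 mussels of high M-named signal), and COX2_mgal_F (0.38), ATP6_mgal_F (0.40), ND4_mgal_F (0.47) and COX3_mgal_F (0.27) were higher, COX2_mgal_F passing in the authors' value table (adjusted p = 0.0498). 57Mgactin (-0.19), 21Meribosomal (-0.14), 14Mgalphatubulin (-0.20), ND2_mgal_M (-0.18) and 89Mgcontactinassociated (-0.45) were lower. The slide as a fixed term left 136 calls and only the groups compared in the fit 15. Within the first scan day 15 rose and 13 fell, and within the second 21 and 23.

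In spring 32 targets rose and 16 fell between 1 and 21 d (limma, 2201 unadjusted, median size 1.08). The contig mgal_nuc_14764 was at least 7.48-fold higher (well above background in 5 of 6 against 0 of 6, adjusted p = 0.0224), and mgal_nuc_33502 rose (4.40, adjusted p = 0.0130, 6 of 6 mussels above the 1 d mean). The latter was well above background in 5 of 6 against 1 of 6, so its size rests largely on background signal at 1 d. The opposite-strand probes of these contigs were well above background on 0 and 1 of 60 arrays. Mussel 4 at 21 d stood apart at -4.49 for mgal_nuc_33502. Both mgal_nuc_30179 (-2.74, SE 0.49, adjusted p = 0.0130) and mgal_nuc_5115 (-2.0, SE 0.46, adjusted p = 0.0417) fell in 6 of 6 mussels relative to the 1 d mean. The difference was -3.32 and -3.65 at the other same-strand probes of the first and -1.12 at the opposite-strand probe of the second. With normexp, whose offset compresses dim signals, mgal_nuc_14764 fell to 1.70 (adjusted p = 0.0833), below the bound of 7.48-fold, and mgal_nuc_5115 to -1.09 (adjusted p = 0.0768). With the slide as a fixed term 0 targets passed (2067 unadjusted), although the 48 kept their signs, with a median size of 1.06 (before 1.08) and a median SE of 0.23 (before 0.23). The named contigs then stood at 4.43 for mgal_nuc_14764 (SE 1.04, before 4.62 and 0.94), 3.93 for mgal_nuc_33502 (SE 0.91, before 0.82), -2.71 for mgal_nuc_30179 (SE 0.52) and -2.03 for mgal_nuc_5115 (SE 0.47), with adjusted p from 0.0573 to 0.0964. The unadjusted count fell from 2201 to 2067 and some SE grew, which raises the adjusted p of calls near the threshold. The count was 21 with normexp, 2 with only the groups compared in the fit, and 15 without spring control 1 d mussel 1 and autumn 10 ug/L 1 d mussel 6, mgal_nuc_14764 (adjusted p = 0.0517) and mgal_nuc_5115 (adjusted p = 0.0813) being lost. Within the first scan day 0 passed (1404 unadjusted), and within the second 3 rose and 2 fell. The M-named list was lower at 21 d by -0.39 (camera adjusted p = 0.12, or 0.00208 with the slide as a fixed term, and 0.558 with an estimated correlation and no slide term). Its direction reversed without spring control 1 d mussel 1 and autumn 10 ug/L 1 d mussel 6. Autumn and spring shared 4 rising targets (0.12 expected) and 2 falling ones (0.06 expected). No named target passed. CYTB_mgal_F (0.21), 64Mgribosomalp0 (0.10), 57Mgactin (0.11), 21Meribosomal (0.09) and 93MgRNAbinding (0.08) were higher. ND4_mgal_F (-0.41), 40Mecollagen (-0.84), CYTB_mgal_M (-0.61) and ND4_mgal_M (-0.59) were lower, CYTB_mgal_M turning to 0.10 without those 2 mussels. COIII_mgal_M was well above background in 0 of 6 mussels at 21 d and 2 of 6 at 1 d, and its lower level rested on spring control 1 d mussel 1, at 7.14.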

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

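Chosen only after the result was seen were the test of male tissue for the M-named signal, all tests of the mitochondrial lists, and the fits without the 2 mussels of high M-named signal. The fit with the slide was set up before, but its bound for mgal_nuc_2301 was set after its result was seen. Chance puts a mussel apart in about 1 in 20 groups of values. Of 65 groups of values tested, 7 held such a mussel, where 3.2 were expected.

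In 2 groups the mean of the M-named mitochondrial targets had a mussel far above the rest. Autumn 10 ug/L 1 d mussel 6 stood at 1.81 with the next at -0.19, and spring control 1 d mussel 1 at 4.07 with the next at -0.06. The other mussels apart from their groups concern single contigs. Autumn control 1 d mussel 1 lay at -6.44 for mgal_nuc_3844 (next 3.63). Spring control 21 d mussel 4 lay at -1.95 for mgal_nuc_35390 (next 1.5) and at -4.49 for mgal_nuc_33502 (next -0.07). Autumn control 1 d mussel 6 lay at 1.82 for mgal_nuc_33049 (next -2.41) and at 1.77 for mgal_nuc_2868 (next -2.60).

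With camera at its preset correlation, 4 tests of a difference in exposure effect between seasons or times passed for the mitochondrial lists. The adjusted p was 0.00277 for the M-named list between seasons at 1 d and 0.00911 for the F-named list between seasons at 21 d. It was 1.83e-05 for the F-named list and 0.012 for the M-named list between 1 and 21 d in autumn. With an estimated correlation the adjusted p of these 4 tests ran from 0.449 to 0.732, and with fry from 0.377 to 0.642. None passed by either, so the data do not establish these differences. The M-named difference between seasons was also lost without the 2 mussels of high M-named signal. The F-named difference between times in autumn was -0.01 in the median within the first scan day and -1.45 within the second.

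The M-named signal rose in these mussels by 2.42 and 4.57 log2 units over the rest of their groups, in 10 of 10 and 9 of 10 targets, and by 5.48 and 11.84 for COIII_mgal_M, each target read at the brightest of its probes. At the other probes this did not always hold: for spring control 1 d mussel 1 the other probes of CYTB_mgal_M ranked it 10 and 36, and those of ND2_mgal_M 33 and 48, of the 60 mussels. Cross-hybridisation from a larger amount of F-named transcripts is argued against, since the F-named mean was not raised in either mussel (-0.15 and -0.51). A difference in the sequence of these transcripts was not tested. Brightness of dim targets on the whole array was looked at in 2 ways. The median rise was -0.03 and -0.07 over 18772 of 22692 targets, those between the lowest and highest M-named mean. The scaling of each array keeps the median of so wide a set small, so it cannot show a rise of dim targets alone. The share of probes well above background does not depend on the scaling. It was 64.7% in the autumn mussel (group 58.5 to 64.9%) and 59.5% in the spring mussel (group 57.9 to 62.9%). Dim targets raised this much over the whole array would bring many more probes above background, so these shares argue against it. Male tissue or a male animal could carry M-type mitochondria and stays open, although the labels call all animals female. Apart from M-named targets the mussels shared 1 target that was rarely high elsewhere, where the 99th percentile of pairs was 5, and no target is named as a male marker, so the test on male tissue or a male animal decides nothing.

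The rise of mgal_nuc_2301 after 21 d of 10 ug/L in spring was 7.31 log2 units with the slide as a fixed term, which argues against the slide. Leaving out each mussel gave an adjusted p of at most 0.00399, which argues against a single mussel. Individual differences unrelated to exposure stay open. Among 100 relabellings of the mussels, the real one included, 45 had as many targets wholly apart by over 4 log2 units as the 4 found here (most 9, median 3). The design gives exposure as the biological candidate, and a shared tank may add to it, with no test that separates them.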

How the results depend on the processing

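Chosen only after the data had been seen were all tests of the mitochondrial lists, the fits without 2 arrays, and the fits within scan days. Over the 12 alternatives run for every comparison, which leave out the fits within scan days and those without each mussel in turn, 171 counts stayed within 1.5 times and 33 moved. Most comparisons had 0 calls, and a count of 0 that stayed 0 was taken as having stayed. The tally thus says little of the comparisons with calls. Of these, the season count at 21 d fell from 817 to 7 with only the groups compared in the fit. Of the values of single targets, run under 11 of these at most, 1407 kept direction and side of the threshold, 60 lost it, 15 gained it and 11 reversed. Of the list tests, run under 7 alternatives that include fry and an estimated correlation, 186 kept both, 27 were lost, 11 gained and 14 reversed. For each change below the cause was not tested, unless given. For 10 ug/L in spring at 21 d, mgal_nuc_2301 stayed past the threshold except with the block on the mussel number (7.52, limma adjusted p = 0.957) and within the second scan day (7.55, limma adjusted p = 0.102). Where it stayed, it ran from 5.04 with normexp, whose offset compresses dim signals, to 7.61 without 1 mussel.

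With normexp 1 target was called for spring 10 ug/L at 21 d, 1 for the season interaction at 21 d and 21 for time in spring. Quantile normalization gave 1 in autumn at 1 d and 1 for the time interaction of 10 ug/L in spring, as did the authors' value table (1 and 1). No filter left 1 for spring 10 ug/L at 21 d, every probe tested separately 1 and array weights 5. The slide as a fixed term left 0 for time in spring. With only the groups compared in the fit, which uses fewer samples, the counts were 1 for spring 10 ug/L at 1 d, 1 at 21 d, 2 between the doses at 21 d, 1 for the season interaction at 21 d, 439 and 7 for the seasons, 15 for time in autumn and 2 in spring. Without the 2 arrays of lowest share well above background 1 was called for spring 10 ug/L at 21 d and 508 between seasons at 21 d, and without the 2 mussels of high M-named signal 3 and 820. The latter fit called 1 for the season interaction at 1 d and 15 for time in spring, the former 0 and 50. The share of season calls at 1 d that were higher was 44.3%, and 50.1% after quantile normalization.

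The mussel numbers do not pair the mussels: 3 of 45 same-numbered pairs correlated over 0.1, with a median of 0.018 (-0.075 to 0.194) against -0.0016 for other pairs. With the number as a replicate block, 1 target was called in autumn at 1 d, 1 for 1 ug/L and 1 for 10 ug/L in spring at 1 d, 0 for 10 ug/L at 21 d, 0 between the doses at 21 d, 1 for the season interaction at 1 d, 0 and 0 for the seasons, 1 for time in autumn and 0 in spring. The groups of a comparison shared 3 or 4 of 6 numbers. With the block, a mussel of unshared number adds nothing to the difference between a pair of groups. Each such fit thus rests on few mussels and loses power. How far this accounts for the lost calls was not tested. Sizes often stayed, as for mgal_nuc_16063 between seasons (11.14 and 11.23) and mgal_nuc_2301 between the doses (8.13). The block reversed 21Meribosomal at 1 ug/L and 1 d (-0.04), COIII_mgal_M at 10 ug/L and 1 d (0.19), ND2_mgal_M at 1 ug/L and 21 d (0.01) and 64Mgribosomalp0 between seasons at 21 d (0).

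In autumn at 21 d, 36Me40Sribosomal turned to -0.01 after quantile normalization and -0.01 in the authors' table. Without the 2 mussels of high M-named signal, 1 ug/L at 1 d gave 0.30 for COIII_mgal_M, 0.29 for COII_mgal_M and 0.29 for COI_mgal_M, 10 ug/L at 1 d gave 0.73 for COIII_mgal_M and time in spring 0.10 for CYTB_mgal_M. Without the 2 arrays of lowest share well above background they stayed at -1.65, -0.83, -1.31, -1.22 and -0.61. The reversals follow from the single mussel left out of the spring controls.

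For the F-named list an estimated correlation gave an adjusted p of 0.303 in autumn at 1 d, 0.131 between seasons at 1 d and 0.288 for time in autumn. With fry these were 0.324, 0.0088 and 0.0979, and the direction at 1 ug/L and 1 d reversed (0.982). The list values that follow are from camera at its preset correlation. Quantile normalization gave 0.00065 in autumn at 21 d, and reversed 1 ug/L at 1 d (0.666), 1 ug/L at 21 d (0.666) and the time interactions of 1 ug/L (0.963) and 10 ug/L (0.96). Normexp brought autumn at 21 d (0.0361), 10 ug/L at 1 d (0.0321) and 10 ug/L at 21 d in spring (0.0246) past the threshold, and reversed 1 ug/L at 1 d (0.446) and 21 d (0.448). The slide as a fixed term reversed 1 ug/L at 21 d (0.952) and its time interaction (0.566). Without the 2 mussels of high M-named signal the time interaction of 1 ug/L reversed (0.482). It was 0.971 without the 2 arrays of lowest share well above background. With those 2 mussels left out the M-named list reversed for 10 ug/L in spring at 1 d (0.177), against 0.145 without the 2 arrays. It also reversed for the time interactions of 1 ug/L (0.239, against 0.4) and 10 ug/L (0.0321, against 0.917) and time in spring (0.309, against 0.109).

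Signal over background limits dim targets: 43.3 to 67.4% of probes were well above it on an array. Log2 differences of targets near background carry wide errors.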

Other observations

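Chosen only after the result was seen were all the counts over other splits of the samples. The tests of the on-off targets were not.

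For each comparison the mussels were split in 100 ways, the real one included. For the seasons only the real split gave as many targets, at 1 d (999, highest other 214) and at 21 d (817, highest other 342). The same held for time in autumn controls (171, highest other 12, and 2579 unadjusted with 2254 as the highest other). No lower number of splits is possible, so with so many counts tested this rank alone does not exclude chance. The calls lay far above the highest other, which argues against chance for these comparisons. Chance was not excluded for time in spring controls, with 5 splits (48, highest other 365) and 12 by the unadjusted count (2201, highest other 3034). For spring 10 ug/L at 21 d 3 splits gave as many calls (2, highest other 100), too weak to exclude chance when so many counts were tested. The count fell to 1 with normexp or no filter, and by the unadjusted count, with 15 splits (1657, highest other 2819), chance was not excluded. For the doses at 21 d it was not excluded, with 18 splits (1, highest other 2).

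Where limma called 0 targets, all 100 splits gave as many, which a count of 0 makes certain, so this tells nothing of chance. The highest other was 2 in autumn at 1 d and 3 in autumn at 21 d, 3 for 1 ug/L and 3 for 10 ug/L in spring at 1 d, 65 for 1 ug/L at 21 d and 3 between the doses at 1 d. It was 1 for the season interactions at 1 d and 1 at 21 d, 6 for the time interaction in autumn, and 134 and 244 for those of 1 and 10 ug/L in spring. By the unadjusted count, 2 splits did as much in autumn at 1 d (1206, highest other 1226), with 1135 expected. Among so many counts a result this low can arise by chance, so chance is not excluded there. The number was 33 in autumn at 21 d (1205, highest other 1987), 67 for 1 ug/L in spring at 1 d (1046, highest other 2988), 60 for 10 ug/L at 1 d (1057, highest other 2482) and 65 for 1 ug/L at 21 d (1055, highest other 3055), none of which excludes chance. The splits with many more calls than the real one separated spring control 21 d mussel 4, with or without mussel 2, from mussels 5, 7, 9 and 10. Of these controls, mussels 4 and 2 lay on slides 3 and 4 and the others on slides 1, 5 and 8, so the splits divided no slide. A structure among these mussels, their arrays or their slides stays open. Mussels 4 and 2 had the brightest arrays of the group, with 75th percentiles of 282 and 272 units against 183 to 206, and mussel 4 the lowest array weight of all 60 (0.59), so array quality stays open as well.

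In 431 of 22462 targets the mussels fell into a high and a low set, with a gap of over 2 log2 units and at least 6 mussels on each side, and in 199 the gap was over 3. They formed 389 groups by shared probe sequence. Season accounted for 3.2% of their variance (highest of the reorderings 2.1%), but the split of 0 targets into high and low mussels followed season by its own test. In limma 6 of the 431 differed between the seasons in controls at 1 d. Sequence variants under single probes may cause such patterns, but where another probe of the target could be read (25 targets) the difference there was 0.75 of that at the probe used (interval 0.64 to 0.79), which argues against variants as the whole cause for those 25. The slide accounted for 11.2% of the variance, and 92 of 100 orderings gave as much, which argues against the slide. Inherited differences between mussels in the presence or activity of genes stay open and were not tested.

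Among 1770 pairs of mussels, the median number of shared targets that were rarely high in other mussels was 0. It was 29 between spring control 1 d mussel 2 and spring 1 ug/L 21 d mussel 2. Of 8937 targets with a probe measured on each strand, the probes correlated across mussels at a median of 0.29, against 0.02 for random pairs. A correlation over 0.5 was found in 28% of them and in 0.3% of random pairs. Of 273 targets that differed between seasons at 1 d at the first probe, 255 had the same sign at the opposite one.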
